A study of Mus musculus with 8 samples.

How the data were processed

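RNA from the hearts of 8 male C57BL/6J mice was hybridised to 8 one-colour (Cy3) Agilent arrays carrying probes for coding and noncoding transcripts. Per the labels' protocols, the mice were 8 to 10 weeks old and weighed 24 to 26 g, the descending aorta was tied against a 26-gauge needle or a sham operation was done, and 1 μg of labelled RNA was used per array. The labels put 4 arrays in the banded group and 4 in the sham group, each array from a separately numbered mouse, 4 weeks after surgery.

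Per the file headers, the intensity of each spot was measured with Agilent Feature Extraction 11.0.1.1, which subtracted the background, removed spatial trends and wrote 1 processed intensity per spot, with no scaling between arrays. The same files give flags for spots well above background, saturated spots and outlier spots, as 0 or 1, per the file headers. A table of the authors' values holds log2 intensities for 60902 probes, and how the authors made it is not given in the sources used here. Against the scanner values of the same array, its columns had log2-scale slopes from 0.984 to 1.02 and correlations of at least 0.9999. The scale of the table is therefore log2. Medians of its columns lay between 4.924 and 4.925, and their other quantiles were not compared. The table was used only as an alternative.

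Each array held 62939 spots, of which 61500 were not controls, for 60930 probes. After 15 negative probes were set aside, 60915 probes remained. The log2 processed intensity was averaged over the unflagged spots of each probe, and each array was centred on its 75th percentile over noncontrol probes. A probe was tested if most of its spots were well above background on at least 4 of the 8 arrays, which left 35785 probes. Banded and sham arrays were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over the tested probes and a threshold of 0.05 on the adjusted p. Input was read with the data.table package (version 1.17.8) and jsonlite, and plots were drawn with Python 3.11.15 and matplotlib 3.10.9. All limma p-values are two-sided. Other p-values came from two-sided exact permutation tests. Arrays that stood apart within a surgery group were found with Dixon's ratio (the gap to the nearest array over the range of the group) against its critical value for 4 samples, which gives no p-value. The number of arrays limits the precision of every comparison.

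The fit was tested on simulated data for the comparison of banded with sham arrays. Known folds were added to 200 of 35684 probes with a value on every array, 50 for each fold. On top of the real arrays, the fit recovered 24% of probes changed 2-fold, 90% of those changed 4-fold and 98% of those changed 8-fold. With the slide row in the model the shares were 26%, 92% and 96%, and with the slide pair as a block 8%, 72% and 78%. In independent noise with the spread of each probe within groups, the shares were 26%, 76% and 98% without a block, 14%, 70% and 86% with the row, and 0%, 18% and 50% with the pair. That spread holds the row and pair differences as random noise, which a block cannot remove.

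Probe names came from the files. The files used here do not pair probe identifiers with gene names, apart from 15 probes, each printed as 20 spots, that carry a RefSeq accession. All 15 matched a gene of a RefSeq table built on GRCm38.p6, which served for names only. No probe coordinates are given. A further 1836 probes carry a lincRNA name (long intergenic noncoding RNA): 649 from mouse lists, 1104 from human lists and 83 from mouse exons. The transcript uc.323, the other ultraconserved transcripts, the pathway lists and the cell type markers chosen before the data were examined were therefore not analysed here, nor was the share of coding against noncoding probes beyond the lincRNA names. The rule for named genes took those past the threshold with no overlap between groups, then those with the smallest p. With no gene past the threshold, all genes that could be named are covered, together with at most 2 probe identifiers in each direction. Values for surgery are written out for some of these genes only.

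All 8 arrays lay on 1 slide and came from 1 scan, so slide and scan blocks could not be fitted. The place of each array was read from its spot positions, as 2 rows of 4. The resemblance of arrays was measured by the correlation of their deviations from the probe means. It was also measured by the spread (median absolute deviation, scaled to an SD) of log2 differences over 15117 probes detected on all arrays and above the 75th percentile. That spread was set against spot noise, taken from genes printed in 20 copies: the SD between copies was 0.0848, which gives 0.120 for a difference. Copies on 1 array leave out noise between arrays. The spread was below this noise for sham 3 and sham 4, and 1.34 times it for banded 2 and banded 3. Unlike the SD of the copies, the spread passes over the few probes that differ most. A ratio near 1 thus leaves room for single probes that changed. In means and SDs of genes each of these pairs was averaged and counted as 1 sample, which leaves n = 3 per group. Banded 1 with sham 2 (0.969 times the noise) and banded 4 with sham 1 (1.17 times) lie across the surgery groups and were not merged. The means, SDs, SEs and p-values with n = 3 take no account of those 2 pairs, so these samples may not be independent. The comparison fixed before the data were examined keeps all 8 arrays, and both versions are given.

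The alternatives were other normalizations (quantile, median centring, cyclic loess, a percentile over detected probes only), the authors' table, other filters on dim probes, flagged spots kept, variance trend and array weights, a replicate block and leaving out each array. Normexp on mean signals was not run, because the mean signal is not among the columns used here. Alternatives chosen after seeing the data included normexp (offset 50) on median signals with quantile normalization, and the slide row and the slide pair as blocks. The others were averaging close arrays of 1 group, and leaving out banded 1 and sham 1. The labels number the mice 1 to 4 in both groups. A probe not well above background on any array of a group has only a bound there: the level of the other group was set against the lowest signal well above background on each array, or the signal of the probe itself where higher.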

Results

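The arrays compared hearts 4 weeks after aortic banding, in which a tie around the descending aorta makes the heart pump against a higher pressure and enlarge, with hearts after sham surgery. The series title concerns how expression of the ultraconserved transcript uc.323 differs in this hypertrophy. That transcript was not analysed here, since the files used here do not pair it with a probe. There were 4 banded and 4 sham arrays. The 75th-percentile signal ran from 143 to 255 units in the banded arrays and from 178 to 206 units in the sham arrays. Between 52.1% and 63.1% of probes lay well above background on each banded array, and between 56.8% and 61.2% on each sham array. No spot was saturated. In all, 29580 probes were well above background on all 8 arrays and 17673 on none.

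The first comparison asks which transcripts differ between banded and sham hearts. Of the 14 named genes that could be tested, 0 passed the threshold, both over all probes and adjusted over the list alone, where the smallest adjusted p was 0.385. Many of these genes are common reference genes for expression work, such as B2m (the light chain of MHC class I), Gusb (a lysosomal enzyme), Actb and Tuba1b (cytoskeleton), Rpl13a (a ribosomal protein), Ppia (a prolyl isomerase), Tfrc (the transferrin receptor), Hprt (purine salvage) and Gapdh (glycolysis). The estimate was above 0 for 10 of them and below 0 for 4, and in 0 of the 14 did the groups stand apart without overlap. For Ldhal6b, a lactate dehydrogenase-like gene, the probe was not well above background on any array, so it has no fold.

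B2m had a log2 level relative to the 75th percentile of 9.23 ± 0.77 (SD, n = 3) in banded and 8.91 ± 0.50 (SD, n = 3) in sham hearts, a ratio of 1.25 with an SE of 0.42 on the log2 scale. Gusb stood at 2.90 ± 0.32 (SD, n = 3) and 2.59 ± 0.38 (SD, n = 3), a ratio of 1.24 with an SE of 0.26. Gk, which encodes glycerol kinase, stood at 0.23 ± 0.46 (SD, n = 3) and 0.54 ± 0.09 (SD, n = 3), a ratio of 0.807 with an SE of 0.25. None of the 3 differences passed the threshold, with a limma adjusted p of 0.995 for each. With all 8 arrays counted separately, the log2 differences were 0.50 for B2m (SE 0.35), 0.46 for Gusb (SE 0.22) and −0.43 for Gk (SE 0.22), with limma adjusted p-values of 0.603, 0.586 and 0.586. Leaving out 1 array gave 0.31 (without banded 3) to 0.83 (without banded 1) for B2m, 0.36 to 0.62 for Gusb and −0.60 to −0.29 for Gk. With the slide row in the model, 6 of the 10 genes with a higher estimate turned to a lower one, among them Actb (log2 difference −0.29) and B2m (−0.02). Gusb was then at 0.16, Gk at −0.24 and Hsp90ab1 at 0.28, and with the slide pair as a block at 0.020, −0.075 and −0.014. Without a block and with all 8 arrays counted separately, Hsp90ab1 was at 0.32 (SE 0.17, limma adjusted p = 0.586). With array quality weights B2m was at 0.78, Gusb at 0.73 and Gk at −0.59. Quantile normalization put B2m at 0.30, Gusb at 0.42 and Gk at −0.44, and the authors' table at 0.30, 0.40 and −0.44.

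**Figure D1:**
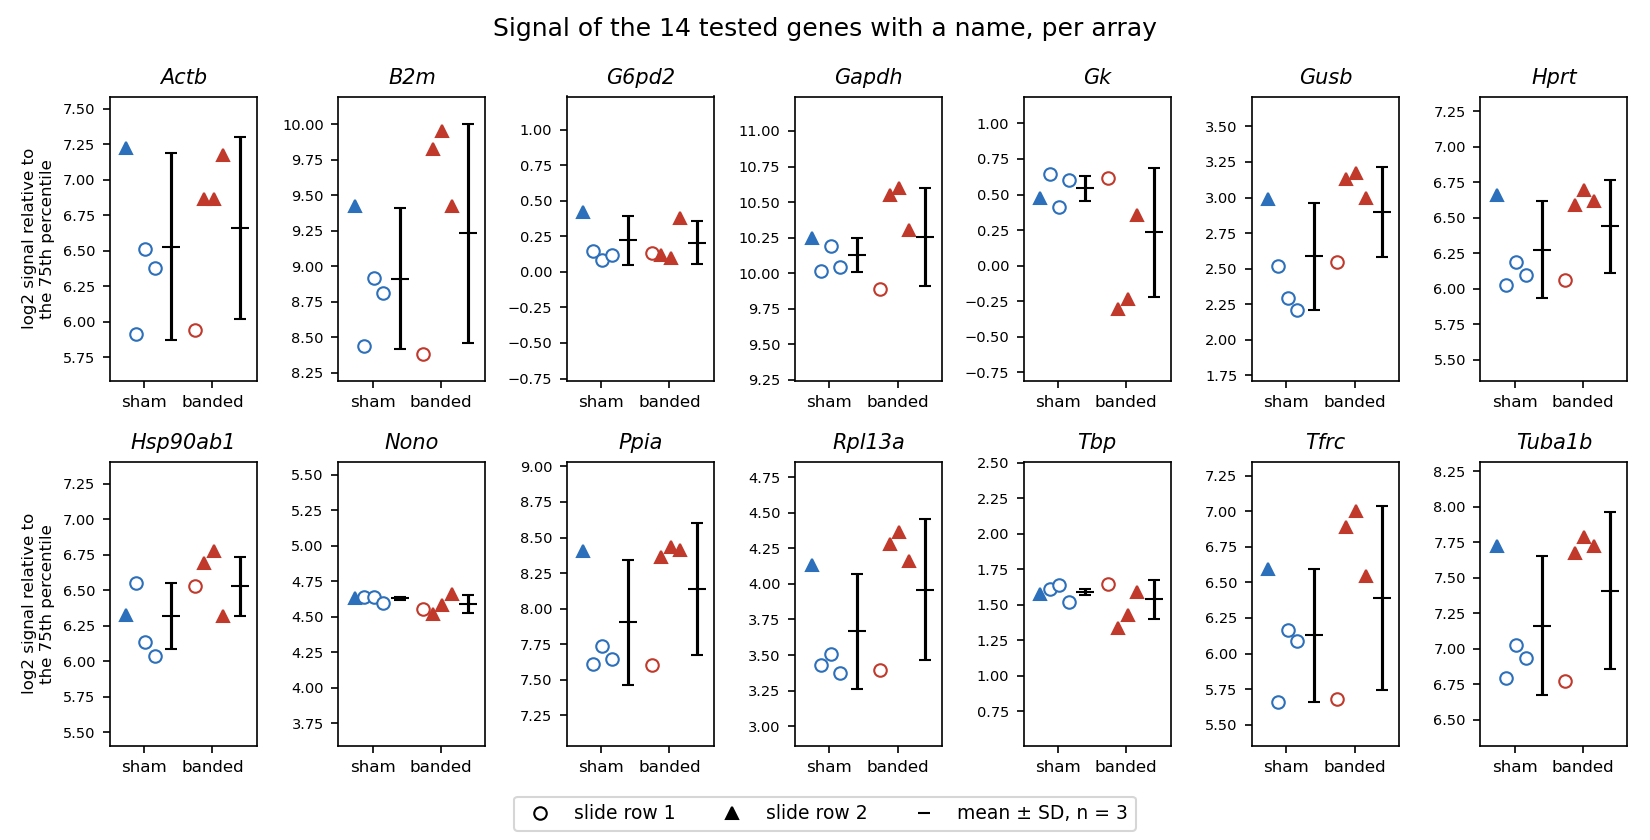
Log2 signal relative to the 75th percentile of each array (vertical axes, each spanning 2 log2 units) for the 14 tested genes with a name, in sham (blue) and banded (red) hearts; open circles are arrays in slide row 1, filled triangles arrays in slide row 2, and black bars the mean ± SD with close arrays of 1 group counted once (n = 3). Genes such as Ppia, Rpl13a and Tuba1b are split by slide row inside both surgery groups, with banded 1 at the level of the sham arrays in row 1 and sham 1 at the level of the banded arrays in row 2.

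Over all 35785 probes tested, 0 were higher and 0 lower in banded hearts at an adjusted p of 0.05 (limma with Benjamini-Hochberg adjustment), and the smallest adjusted p was 0.0901. At an unadjusted p under 0.05, 1142 probes were higher and 1391 lower, which is 7.08% of the probes tested. That total of 2533 rested on single arrays: it was 7110 without banded 1 (4226 higher, 2884 lower), 4648 without sham 1 (2868 higher, 1780 lower), 1370 without banded 3, 1322 without sham 3, 1071 without sham 4 and 851 without banded 2. With array quality weights it was 12362 (6713 higher, 5649 lower). The lowest weights fell on banded 1 (0.37) and sham 1 (0.44), and the highest on sham 4 (2.97). Banded 1 and sham 1 alone keep surgery apart from slide row. The weighted count and those without banded 1 or without sham 1 thus take in more of the row difference described below. They cannot be credited to surgery alone. Of the 2533, 125 were at least 2-fold higher and 76 at least 2-fold lower. The median size of a log2 difference was 0.21 and the median SE 0.21. With the slide row in the model the count past the threshold was again 0, with 1978 probes at an unadjusted p under 0.05. With close arrays of 1 group counted once it was 0, with 726.

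The probe with the smallest p, ASMM10P011458, was well above background on 4 of 4 banded arrays and on 0 of 4 sham arrays. Its processed signal ran from 25.3 to 63.4 units in banded and from 3.16 to 4.56 units in sham hearts, so it was at least 2.29-fold higher in banded hearts (limma adjusted p = 0.0901, past no threshold). The next on the higher side, ASMM10P032090, had a ratio of 1.82. On the lower side ASMM10P041974 had a ratio of 0.589. The limma adjusted p of these was 0.586, as was that of ASMM10P005855, also lower, which has no fold here because it was well above background on only 1 of 4 banded and 3 of 4 sham arrays. Across all probes considered, 5 were well above background on all 4 banded arrays and no sham array, and 16 on all 4 sham arrays and no banded array.

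Probes with lincRNA names formed the noncoding group that could be told apart. Of 1836 such probes, 605 (33.0%) were bright enough to test, against 59.5% of the other probes. At the threshold, 0 of the 605 were called, both over all probes and adjusted over the group alone (smallest limma adjusted p = 0.474). At an unadjusted p under 0.05, 8 were higher and 53 lower in banded hearts. Their median log2 difference was −0.17, against 0.01 for the other probes. Per array, the median of lincRNA-named probes relative to other probes lay between −1.28 and −1.14 in banded and between −1.13 and −1.01 in sham hearts. The difference of the group means was −0.12 (exact permutation p = 0.0286, the smallest that 70 assignments of 4 against 4 can give). It was −0.11 within slide row 1 and −0.10 within slide row 2, where 1 array stands on one side each. With the row as a block it was −0.10 (exact permutation p = 0.188 over 16 assignments). With the slide pair as a block it was −0.04 (exact permutation p = 0.5, the smallest that 4 assignments can give, so that test cannot decide). With normexp on median signals and quantile normalization together it was −0.06 (exact permutation p = 0.0571). Under planned settings it was −0.13 after quantile normalization and in the authors' table (exact permutation p = 0.0571 each), −0.11 with cyclic loess (0.0857) and −0.13 with no filter on background (0.286). Leaving out any 1 sham array gave −0.14 to −0.09 (exact permutation p = 0.0571 each), and any 1 banded array −0.15 to −0.10 (0.0286 each). Between slide rows the same measure differed by −0.09 (row 2 minus row 1, exact permutation p = 0.143). Against probes matched on mean level the surgery difference was −0.08 (exact permutation p = 0.143). With close arrays counted once it was −0.10 (exact permutation p = 0.1, the smallest possible with 3 against 3).

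The place of the arrays on the slide was compared in the same way. Each row holds arrays named banded and arrays named sham in the labels. Row 1 held banded 1 and sham 2, 3 and 4, and row 2 held banded 2, 3 and 4 and sham 1. Tuba1b was 1.80-fold, Rpl13a 1.75-fold, Ppia 1.69-fold, B2m 2.03-fold and Tfrc 1.81-fold higher in row 2 than in row 1, over 4 arrays per row. Actb (1.79-fold), Gusb (1.61-fold) and Hprt (1.46-fold) were past the threshold as well, so 8 of the 14 genes were higher in row 2, with limma adjusted p-values from 0.000832 to 0.00943. Gapdh had a ratio of 1.31 (limma adjusted p = 0.0650), and Nono, Tbp, Hsp90ab1, G6pd2 and Gk did not pass. With each close pair of arrays counted as 1 sample (2 per row), 0 of the 14 genes passed, and the smallest limma adjusted p was 0.0841. Control probes for the 3′ and 5′ parts of a transcript, a sign of RNA quality and labelling, were compared between rows with all 8 arrays counted separately. The 3′ over 5′ difference of mouse PGK1 was 4.04 log2 units in row 1 and 4.46 in row 2 (exact permutation p = 0.0286, the smallest that 70 assignments can give). That of mouse GAPDH was 0.43 and 0.62 (exact permutation p = 0.0571). For PGK1 the arrays of a close pair were alike, such as banded 1 (3.85) and sham 2 (3.90), or banded 4 (4.39) and sham 1 (4.39). Arrays of a pair may not be separate samples, so these p-values may be too small.

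Over all probes, 4492 were higher and 2543 lower in row 2 at an adjusted p of 0.05 (limma), and 1004 and 423 with each close pair counted once. After quantile normalization the counts with 8 arrays were 3659 and 3198, and 6174 probes were called in the same direction under both normalizations. The first principal component held 47.9% of the variance and separated the rows, with banded 1 among the sham arrays of row 1 and sham 1 among the banded arrays of row 2. Within surgery groups, the row difference among banded arrays and that among sham arrays had a correlation of 0.654 across 35684 probes, which are not independent replicates. The surgery difference within row 1 and that within row 2 had a correlation of 0.153 across the same probes. These surgery differences share no close pair, so the 0.153 and the 0.654 are not alike.

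Each array resembled 1 neighbour on the slide most: banded 1 with sham 2, sham 3 with sham 4, banded 2 with banded 3, and banded 4 with sham 1. Over bright probes, log2 differences within these pairs spread 0.969, 0.990, 1.34 and 1.17 times as widely as spot noise. In the other 24 pairs of arrays they spread 2.61 to 5.26 times as widely. For banded 1 and sham 2, which come from different surgery groups, the spread was below spot noise, as it was for sham 3 and sham 4. The spread passes over the few probes that differ most. Single probes were counted over 35684 tested probes with a value on every array, dim ones included. In banded 1 against sham 2 and in banded 4 against sham 1, 19 of these probes were at least 2-fold higher in both. A further 25 were at least 2-fold lower in both, and 19 changed in opposite directions. Sham 3 and sham 4 were counted as 1 sample in the gene means above, and so were banded 2 and banded 3. Over the 14 named genes, the median size of the log2 difference was 0.03 between banded 1 and sham 2 and 0.03 between banded 4 and sham 1. It was 0.08 between banded 2 and banded 3 and 0.10 between sham 3 and sham 4.

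**Figure D2:**
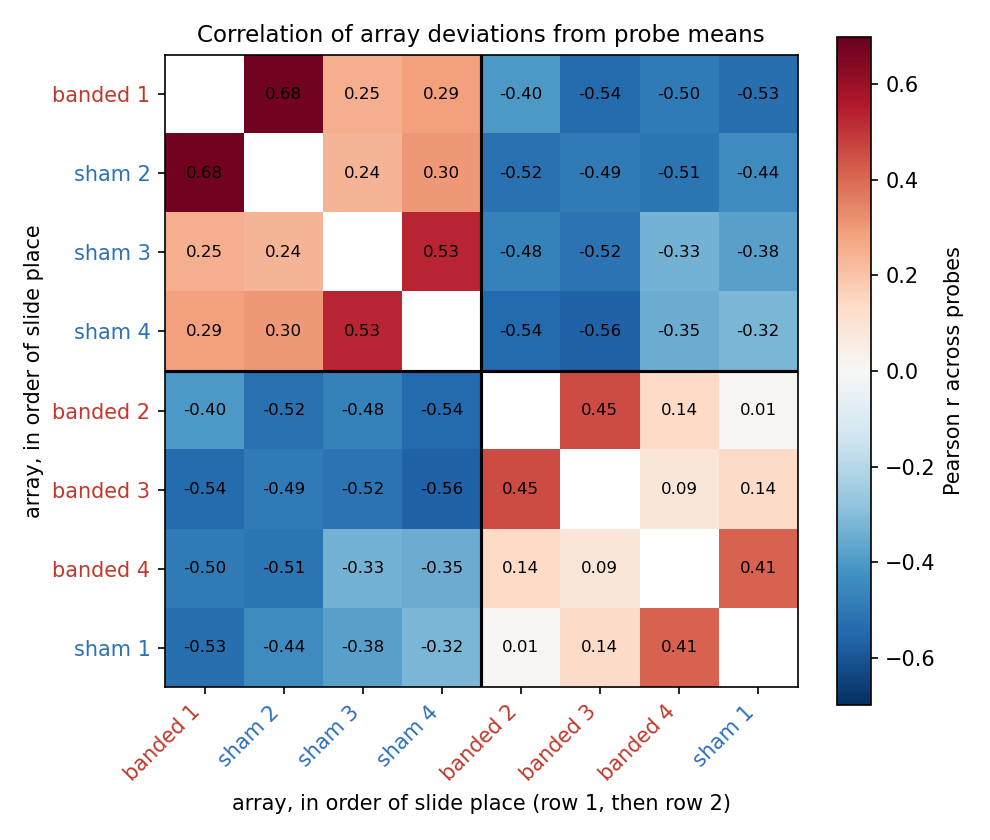
Pearson correlation across probes of the deviations of each array from the probe means, with arrays on both axes in order of slide place (row 1, then row 2, parted by black lines; names in red for banded and blue for sham). Correlations lie between 0.01 and 0.68 inside a row and between −0.56 and −0.32 across rows, whatever the surgery group.

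Every division of the 8 arrays into 4 and 4 was then fitted in the same way with limma. The slide row split gave 11663 probes at an unadjusted p under 0.05 and 7035 past the threshold, and the banded and sham split 2533 and 0. It ranked in place 5 of 35 by the first count, and no split other than the slide row had a probe past the threshold.

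**Figure D3:**
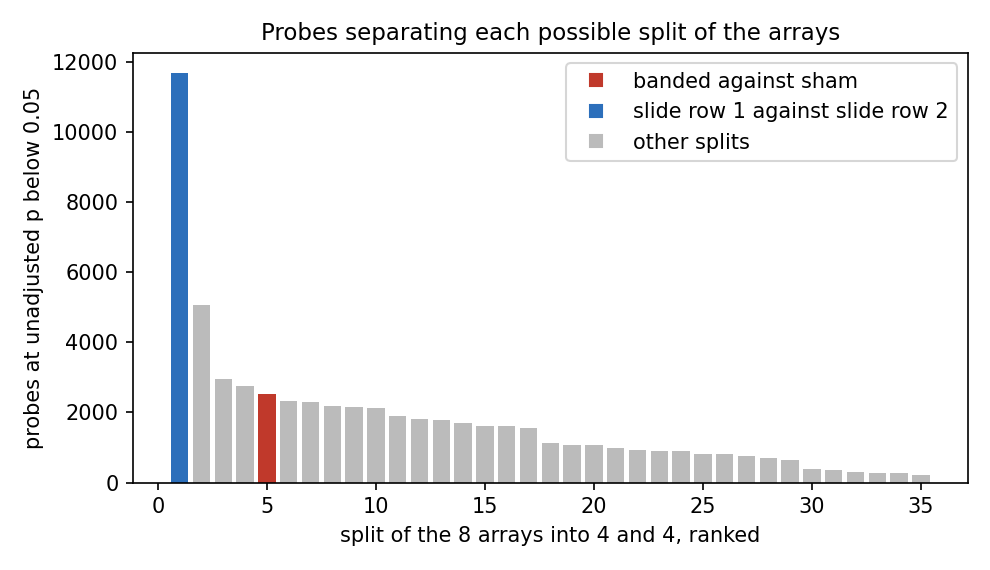
Number of probes at an unadjusted p under 0.05 (vertical axis) for each of the 35 divisions of the 8 arrays into 4 and 4, ranked (horizontal axis). The bar for slide row 1 against row 2 (blue) reaches 11663, the bar for banded against sham (red) 2533, and the other divisions are grey.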

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

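All tests that weigh explanations here were chosen after the results were seen. In 48 groups of 4 arrays, 7 held an array that stood apart from the other 3 by most of the range of its group (Dixon's ratio past its critical value), where chance gives about 1 in 20 groups. In the banded group, banded 1 was lowest for Hprt (6.06, the next array 6.59), Ppia (7.60, next 8.36) and Tuba1b (6.77, next 7.68), in log2 units relative to the 75th percentile. In the sham group, sham 1 was highest for Ppia (8.41, next 7.74) and Rpl13a (4.13, next 3.50). Banded 4 was highest in its group for G6pd2 (0.38, next 0.13). Sham 4 was highest in its group for the lincRNA-named probes relative to other probes (−1.01, next −1.12).

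The first 5 of these follow the main pattern of the series: arrays grouped by slide row and not by surgery. The surgery groups as named in the labels do not give this grouping. Arrays of 1 surgery group in different rows had correlations of deviations of at most −0.322, while arrays of different groups in 1 row had at least 0.00640. These correlations restate the pattern and are no separate test of it. A slide row batch could account for it. The row difference within banded arrays and within sham arrays correlated at 0.654 across probes, but shared close pairs raise that value without a row effect. Exchanged names of banded 1 and sham 1 could account for it too, as each then has its nearest array in its own group (correlations 0.677 and 0.410). The same holds after an exchange of sham 2 and banded 4, so nearest arrays do not single out 1 exchange. The latter division cuts across the rows and gave 5063 probes at an unadjusted p under 0.05 (limma), with 0 past the threshold. The lincRNA shift had the sign of the labelled comparison in both rows (−0.11 and −0.10), with 1 array on one side in each. The 3′ over 5′ difference of the PGK1 control probes differed between rows (4.04 and 4.46 log2 units). Neither excludes the batch or the exchange of banded 1 and sham 1. That exchange and the slide row give the same division of the 8 arrays, so these cannot be told apart. A surgery effect under exchanged names stays open.

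The second pattern is the 4 close pairs of neighbouring arrays. A gradient along the slide is argued against, since side-by-side arrays outside the pairs differed by at least 2.71 times spot noise. The same RNA on both arrays of a pair could give it, as the largest difference within a pair was 1.34 times spot noise. Arrays handled in batches of 2 could give it too, if the mice themselves differed little, as arrays of 1 row outside the pairs differed by at least 2.61 times spot noise. Each pair occupies 1 pair of places, so the same RNA and a batch of 2 cannot be told apart, and with surgery as named 2 of the 4 pairs hold 1 banded and 1 sham array.

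The third pattern is that no probe passed the threshold between banded and sham hearts. Of the 35 splits of the 8 arrays into 4 and 4, 5 gave at least as many probes at an unadjusted p under 0.05 as the surgery split (2533, limma, with 0 past the threshold), so chance cannot be excluded for that number. The highest other split gave 11663, several times the surgery count, and was the slide row split, which points to a structure of the samples. That the slide row hides a surgery difference is not borne out by the count, since with the row in the model 0 probes passed and 1978 had an unadjusted p under 0.05. It stays open, since that fit recovered 26% of 2-fold and 92% of 4-fold changes added to the real arrays. With the slide pair as a block, 72% of 4-fold changes were recovered there. In independent noise the shares were 14% and 70% with the row, and 18% of 4-fold changes with the pair. That noise holds the row and pair differences as random spread, which a block cannot remove. These last shares therefore do not measure what the blocked fits recover on the real arrays.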

How the results depend on the processing

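Alternatives with the slide row, the slide pair, averaged close arrays, and banded 1 and sham 1 left out were chosen after seeing the data. So was normexp on median signals with quantile normalization. The count of probes past the threshold stayed at 0 in 21 of 25 alternative fits. It was 1 with array quality weights, 0 to 2 when 1 array was left out (2 without banded 1 and 1 without banded 2), and 3839 without both banded 1 and sham 1 (2697 higher, 1142 lower), 18 of them with lincRNA names. Every banded array is then in slide row 2 and every sham array in row 1, so surgery and row cannot be told apart there. In that fit 7 genes passed, among them B2m (1.01), Rpl13a (0.83) and Tuba1b (0.81), as log2 differences. The number at an unadjusted p under 0.05, 2533 with all arrays, ran from 726 with close arrays averaged to 12362 with array quality weights, and was 7110 without banded 1 and 851 without banded 2. Lower estimates outnumbered higher ones with all arrays (1391 against 1142), and the balance turned with the weights (5649 against 6713), without banded 1 (2884 against 4226), without sham 1 (1780 against 2868), without both (4254 against 6033) and, barely, without sham 2 (1238 against 1244) and with no filter on background (1357 against 1384). At an unadjusted p under 0.05 with a fold of at least 2, without adjustment, the count was 201.

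G6pd2, at −0.01 on the log2 scale, turned to 0.039 with array quality weights and to 0.084 without banded 1 and sham 1, and ran from −0.074 to 0.068 when 1 array was left out, above 0 in 4 of 8 such fits. With the slide row block, Actb turned to −0.29, B2m to −0.016, Hprt to −0.033, Ppia to −0.034, Tfrc to −0.036 and Tuba1b to −0.068. With the slide pair block, which compares surgery inside the 2 mixed pairs, Actb turned to −0.0091, B2m to −0.029, Gapdh to −0.039, Hprt to −0.0024, Hsp90ab1 to −0.014, Ppia to −0.0012, Rpl13a to −0.0024, Tfrc to −0.013 and Tuba1b to −0.0081, and Tbp to 0.022. The cause was not tested. None of the 14 genes passed in the other 24 fits. Normalization changed the size of some estimates. After quantile normalization B2m went from 0.50 to 0.30, Ppia from 0.35 to 0.22 and Gapdh from 0.21 to 0.07, while Gk went from −0.43 to −0.44. The shift of lincRNA-named probes stayed below 0 in all 20 alternatives that could change it (−0.15 to −0.04, the latter with the slide pair block), with exact permutation p-values from 0.0286 to 0.5, of which 6 were under 0.05. With the replicate block the p was 0.125, the smallest that 16 assignments can give. The numbers of the mice did not pair the arrays: deviations of same-numbered arrays from their own group means had correlations of −0.654, −0.199, −0.153 and −0.053. The first, for banded 1 and sham 1, is the row correlation of 0.654 with its sign turned, and so no separate evidence. With the replicate block 0 probes passed, with 1423 at an unadjusted p under 0.05 (limma). Planned fits not run were normexp on mean signals, slide and scan blocks (1 slide, 1 scan), and those for uc.323, ultraconserved transcripts and gene lists, with their set tests. Dim probes are limited by signal over background: 17673 of 60915 probes were well above it on no array.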

Other observations

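The values here were picked out after the data were seen. A control probe for a rat transcript, Rat-PGK1_3, stood at −1.13 and −1.19 on the log2 scale relative to the 75th percentile in sham 3 and sham 4. In the other 6 arrays it lay between −4.60 and −4.12 and was well above background on 0 of them, so no fold is given. Sham 3 and sham 4 are 1 of the close pairs. Between banded and sham hearts the 3′ over 5′ difference of the mouse PGK1 control probes was 4.32 and 4.18 log2 units (exact permutation p = 0.486), and for mouse GAPDH the exact permutation p was 0.6.

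In all, 20 probes stood at least 2 log2 units above or below all other arrays in both members of a close pair, 13 of them in banded 2 and banded 3. Over the other 24 pairs of arrays there was 1 such probe. The consensus correlation within slide pairs, estimated by limma with surgery alone in the model, was 0.691. Each pair lies within 1 row, so the row difference enters this value. Between slide rows, 63 probes were well above background on all arrays of row 2 and none of row 1, and 204 the other way round, against 5 and 16 between banded and sham hearts.

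Of the 35 splits of the arrays, 3 held a probe with a p as small as the 2.52e-06 of ASMM10P011458, the surgery split included.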
